A study of Mus musculus with 6 samples.

How the data were processed

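The data were RNA-seq profiles of mouse pulmonary microvascular endothelial cells in 2 groups of 3 samples each, grouped by the titles of the samples. Per the labels' protocols, RNA was extracted with TRIzol reagent and total RNA was the input. The submitters' processing notes list HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 and the genome build GRCm38.p6, without saying which step used which. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. For 55232 features, the deposited table gave raw read counts per sample, which are whole numbers. The deposited FPKM equal the count divided by the feature length and by 1 constant per sample, within 0.1% for 100% of the values. That constant was 0.981 to 1.04 times the column total, so the authors had applied a scaling factor per sample, and the FPKM were not used for tests. The deposited log2 fold change is the repletion group over control, by its sign against the counts for 100% of features with a deposited adjusted p under 0.05. The deposited p-values and adjusted p-values, named so per the file headers, were given for 24680 features, all with a summed count of at least 2, and 6222 adjusted values were exactly 1. Of the features, 700 carry no Ensembl identifier, and these held 0.133% to 0.208% of a library's counts.

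The depth was 15582349 to 17817618 counts per sample. Positions are those of the deposited table in GRCm38. Transcript sequences, exon numbers and GC content came from GENCODE release M21 on the same build, which held 99.9% of the Ensembl identifiers, 98.3% of them with the same start and end. Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Features were filtered with filterByExpr by group, which left 13804 and removed 41428. Counts were scaled with TMM factors of 0.970 to 1.03 and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 14.1%. The standard error (SE) of a log2 fold change was derived from its F statistic, and CPM are TMM-scaled with SD over 3 samples unless stated otherwise. Summed marker levels, counts of features removed by the filter and levels per kilobase are CPM of the unscaled library total.

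Before the data were examined, 26 gene lists were fixed, covering HMGB1-related genes, endocytosis, lysosome and autophagy, inflammasome, NF-kB activation, interferon response, endothelial identity, junctions, coagulation, hypoxia, NRF2, the integrated stress response, ER stress, heat shock, cell cycle, p53, sterol synthesis, TGF-beta and matrix, immediate early genes, nuclear and mitochondrial respiratory genes, and markers of tubular, leukocyte, fibroblast, lung epithelial and lymphatic cells. The 23 lists with at least 5 tested members were tested with limma's camera on voom values, two-sided, with a preset correlation of 0.01 and beside it an estimated one. Members past the threshold were counted over all tested features and adjusted over the list alone. The rule for named genes took the 6 largest rises and 6 largest falls among protein-coding genes past the threshold with a mean log2 CPM of at least 1 and groups that did not overlap. It also took the member of each list with the smallest p in each direction, and Hmgb1, Tlr4, Ager, Cav1, Cltc, Cdh5, Pecam1, Icam1 and Vcam1. Other genes printed as examples, and 5 further lists used after the report, were chosen after their values were seen. The values of 1 gene that the rule took are not reported here.

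The share of counts in mitochondrially encoded genes was compared with an exact permutation test. Near-identical copies were sought among annotated transcripts with BLAST 2.17.0 at 95% identity. Matches had to span at least 100 bases for mitochondrial genes and at least 30% of the longest transcript for named genes. Of 113 named genes, 15 had such a copy and 52 overlapped another annotated feature. List medians were compared with 10000 random lists matched on abundance and length. Non-coding features, with those of biotype TEC or without an annotated biotype counted among them, were placed by their distance from tested protein-coding genes. Distances went up to 10 kb, and 100000 permutations were used. The alternatives were DESeq2, limma-voom, RLE, upper quartile or library size only, no filter or a minimum of 1 CPM in 3 samples, protein-coding genes only, a block for the replicate number, each replicate left out, and fry for lists. Added after the data were seen were removal of each library's trend with gene length and GC content, of features without an Ensembl identifier, and of mitochondrial features. The test was tried on simulated counts for this comparison: over 13512 genes, it recovered 37.3% of 67 genes changed 1.5-fold, 67.2% of 67 changed 2-fold and 81.8% of 66 changed 4-fold, with 7 false among 131 calls. The simulation changed far fewer genes than were called in the data, so its adjusted threshold was stricter and its shares can understate recovery there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.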

Results

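RNA was measured by sequencing in mouse pulmonary microvascular endothelial cells, labelled as a cell line and taken from the lower chamber of a co-culture after 12 h. In the control group, 3 samples had shared the culture with untreated TCMK-1 cells, a mouse kidney tubular epithelial line. In the other group, called the repletion group here, 3 samples had shared it with TCMK-1 cells that had regained ATP after ATP depletion, which the labels abbreviate as IR. The libraries held 15582349 to 17817618 counts and between 17899 and 22130 features with at least 1 count. Nothing in the labels says that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Counts of replicates of a group differed by more than sampling noise, with a chi-square of 9.20 to 26.0 per feature, and each sample was counted once.

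The comparison asks how lung endothelial cells differ after co-culture with kidney tubular cells that went through energy loss and recovery, in a study whose title concerns HMGB1 taken up by these cells. In the repletion group, most tested antioxidant, integrated stress response, p53, lysosomal, interferon-stimulated and nuclear respiratory chain genes were lower, with list medians between -0.73 and -0.45 on the log2 scale. Most mitochondrially encoded mRNAs were higher, with mt-Nd1 up 8.04-fold, and Thbs1, a matrix protein gene, was up 3.53-fold. The caveolin gene Cav1 and the HMGB1 receptor gene Tlr4 were higher, while the endocytosis and HMGB1-related lists did not pass as wholes. Hmgb1 itself stood at 229 ± 18.1 CPM in control and 255 ± 9.69 in the repletion group (SD, n = 3), a log2 fold change of 0.15 ± 0.10 (SE) with an adjusted p of 0.235 in edgeR's quasi-likelihood test. Of 13804 tested features, 2830 rose and 2654 fell at an adjusted p under 0.05, and 1039 and 382 of these changed at least 2-fold.

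The largest rises chosen by the naming rule were in Rnf225, Usp17lb, Fbn1, Ppp1r10, Apol8 and Lbhd1, from 5.38 for Rnf225 to 4.09 for Lbhd1 on the log2 scale. Control counts were 0, 2 and 4 for Rnf225 and 1, 4 and 2 for Usp17lb. They were 1, 8 and 11 for Apol8 and 9, 5 and 10 for Lbhd1. The size of these rises thus rests on few control reads. Ppp1r10 (ENSMUSG00000039220, chromosome 17, 35916434 to 35932283 in GRCm38, 20 exons), which encodes a regulatory subunit of protein phosphatase PP1, went from 2.53 ± 0.883 CPM to 56.0 ± 8.99 (SD, n = 3). Its log2 fold change was 4.48 ± 0.21 (SE), with an adjusted p of 1.1e-09 in edgeR's quasi-likelihood test. Fbn1 (chromosome 2, 125300594 to 125507993), the gene of the microfibril protein fibrillin 1, rose by 4.51 ± 0.39, with counts of 5, 4 and 5 in the control libraries and 131, 97 and 105 in the repletion libraries. Usp17lb rose by 4.66 ± 0.91 with 157, 10 and 27 counts in the repletion libraries, by 2.90 without repletion replicate 1, 3.81 with limma-voom, 4.08 with a block for the replicate number and 5.27 without control replicate 2. The largest falls were in Cox6a2, Gsta1, Gm3776, Gm19410, P2rx3 and Syt12. Cox6a2 (chromosome 7, 128205435 to 128206387), which encodes a cytochrome c oxidase subunit, fell by 4.35 ± 0.57, from 4.64 ± 0.389 CPM to 0.216 ± 0.268, with 9, 1 and 1 counts in the repletion libraries. Gm19410 fell by 3.49, and P2rx3 and Syt12 fell by 3.11 each. Gsta1 and Gm3776, glutathione S-transferase genes, fell by 3.66 and 3.51, but their transcripts are 99.5% identical and reads could be divided between them. Leaving out 1 library moved some of these fitted values by over 1.5-fold: Rnf225 rose by 6.24 without control replicate 3, Cox6a2 fell by 6.08 and Syt12 fell by 3.76 without repletion replicate 1, and Gsta1, Gm3776 and Gm19410 fell by 4.38, 4.82 and 4.10 without repletion replicate 2. Rnf225, Fbn1, Ppp1r10, Lbhd1, Cox6a2, Gm19410, P2rx3 and Syt12 overlap other annotated features, Rnf225 and Ppp1r10 on the same strand only, so their values are uncertain.

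Antioxidant and metabolic stress genes were lower in the repletion group. Of 24 tested NRF2 target and antioxidant genes, 1 rose and 20 fell (1 and 20 adjusted over the list alone), against 20.5% and 19.2% of all tested features. Nqo1 (chromosome 8, 107388225 to 107403206), a quinone reductase gene, fell by 1.41 ± 0.12, Srxn1 fell by 1.02 and the heme oxygenase gene Hmox1 fell by 0.73, while the cystine transporter gene Slc7a11 rose by 0.89. Camera gave the list an adjusted p of 1.2e-09, and adjusted p = 0.0543 with an estimated correlation. Of 23 integrated stress response genes, 17 fell and the others did not pass (17 adjusted over the list alone). Ddit3 (chromosome 10, 127290774 to 127296288), which encodes the transcription factor CHOP, fell by 2.10 ± 0.15, Trib3 fell by 1.31, and the asparagine synthetase gene Asns fell by 1.27. Camera gave an adjusted p of 2.4e-08, and adjusted p = 0.200 with an estimated correlation. Of 22 p53 and apoptosis genes, 1 rose and 12 fell (1 and 12 adjusted over the list alone). Btg2 fell by 2.43, Trp53inp1 fell by 1.56 and the cell cycle inhibitor gene Cdkn1a fell by 0.93, while the survival gene Bcl2 rose by 1.23. Camera gave an adjusted p of 3.5e-05, and adjusted p = 0.200 with an estimated correlation.

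Lysosomal, interferon-stimulated and respiratory chain genes also fell. Of 29 lysosomal and autophagy genes, 1 rose and 19 fell (1 and 19 adjusted over the list alone). The autophagy receptor gene Sqstm1 fell by 0.85, the protease genes Ctsb and Ctsl fell by 0.87 and 0.70, and Lamp1 fell by 0.65. Uvrag rose by 0.45, or 0.28 after removal of the trend with gene length and GC content. Camera gave an adjusted p of 6.7e-07, and adjusted p = 0.0635 with an estimated correlation. Of 32 interferon-stimulated genes, 2 rose and 19 fell (2 and 21 adjusted over the list alone). Ifi44 went from 127 ± 33.7 CPM to 40.4 ± 11.8 (SD, n = 3), Usp18 fell by 1.49 and Irf7 fell by 1.03, while the RNA sensor gene Ifih1 rose by 0.50. Camera gave an adjusted p of 6.7e-07, and adjusted p = 0.601 with an estimated correlation; fry gave 0.0521, with a range of 1.3e-09 to 0.601 over the list's alternatives. Of 31 nuclear-encoded respiratory chain genes, 21 fell and the others did not pass (21 adjusted over the list alone), with Ndufb8, a complex I subunit gene, among those lower: it fell by 1.03 ± 0.16. Uqcrb and Cycs fell by 0.81 and 0.72, but have near-identical copies, so these values are uncertain. Camera gave an adjusted p of 2.7e-07, and adjusted p = 0.458 with an estimated correlation, and the list median went from -0.47 to -0.26 after removal of the length and GC trend.

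**Figure D1:**
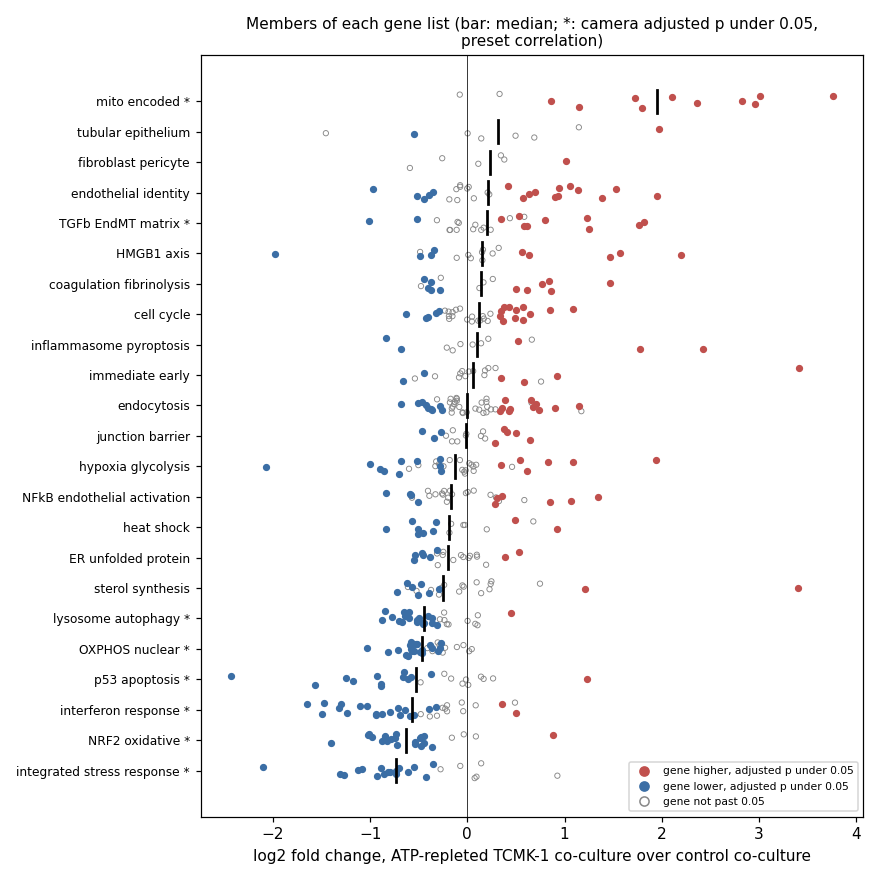
Each point is a tested member of a gene list, placed by its log2 fold change in the repletion group over control on the horizontal axis, in red if it rose, blue if it fell and open if it did not pass, with black bars for list medians and a star for lists that passed camera. The medians run from -0.73 for the integrated stress response to 1.95 for mitochondrially encoded mRNAs.

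Mitochondrially encoded mRNAs moved in the other direction. Of 12 tested mitochondrially encoded mRNAs, 10 rose and the others did not pass (11 adjusted over the list alone), with a median log2 fold change of 1.95. On the mitochondrial chromosome, mt-Nd1 (2751 to 3707) rose by 3.01 ± 0.15 (SE), mt-Cytb rose by 2.36, mt-Nd4 by 2.10 and mt-Nd6 by 0.87. The most abundant, mt-Co1, had a log2 fold change of -0.08 with an adjusted p of 0.584 in edgeR's quasi-likelihood test. mt-Co2 stood at 0.33 with 0.0786, and passed without control replicate 1 (0.00859), without repletion replicate 1 (0.0386), with library size only and after removal of the length and GC trend, with a range of 0.00169 to 0.376 over its alternatives. The ribosomal RNA mt-Rnr1 fell by 1.83 and mt-Rnr2 fell by 0.72. Of the 12 mRNAs, 9 share at least 100 bases at 95% identity with other annotated genes, so their counts are uncertain. Camera gave the list an adjusted p of 9.6e-10, and adjusted p = 0.212 with an estimated correlation. Mitochondrially encoded protein-coding genes held 1.63% ± 0.0405 of library counts in control and 2.5% ± 0.283 in the repletion group (SD, n = 3), with a two-sided exact permutation p of 0.1, the smallest possible with 3 against 3.

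**Figure D2:**
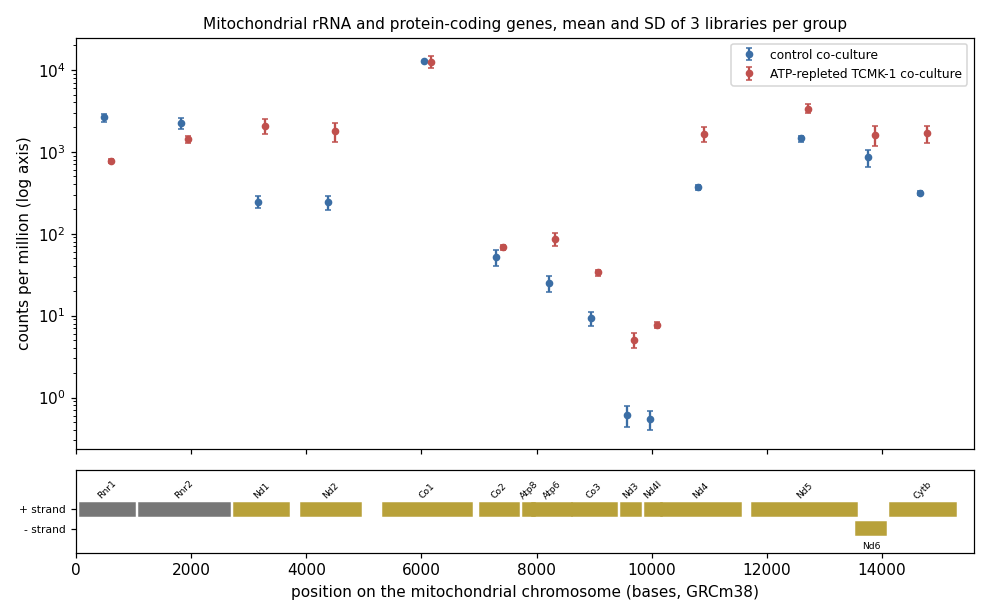
CPM of the unscaled library total, on a log axis, for ribosomal RNA and protein-coding genes by position on the mitochondrial chromosome, with means and SD of 3 libraries in control (blue) and in the repletion group (red); mt-Atp8, under 0.5 CPM, is not drawn. mt-Nd1 stood at 246 in control and 2062 in the repletion group, and mt-Rnr1 at 2634 and 773.

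Genes of TGF-beta signalling and matrix were in part higher. Of 24 such genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone). Thbs1 (chromosome 2, 118111876 to 118127133), the gene of the matrix protein thrombospondin 1, went from 303 ± 9.61 CPM to 1071 ± 87.3 (SD, n = 3), and Ctgf, Tgfb2 and Cyr61 rose by 1.76, 1.25 and 1.23. S100a4, which shares sequence with Gm42674, fell by 1.02, and did not pass after removal of the length and GC trend (log2 fold change of -0.67, adjusted p of 0.0563, with a range of 3.8e-06 to 0.0563 over its alternatives). Camera gave the list an adjusted p of 0.0383, and adjusted p = 0.212 with an estimated correlation. The call was also lost without control replicate 1 (0.0594), without repletion replicate 3 (0.0576) and after removal of the length and GC trend (0.0672), with a range of 0.00196 to 0.212 over its alternatives, and the list median of 0.20 was 0.10 and 0.08 without those replicates.

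HMGB1-related genes moved both ways. Of 18 of them tested, 5 rose and 4 fell (5 and 4 adjusted over the list alone), with a camera adjusted p of 0.552; fry, which asks whether the genes move one way on balance, gave 0.0166, with a range of 0.0166 to 0.725 over the list's alternatives. Tlr4 (chromosome 4, 66827584 to 66930284), a receptor gene, went from 121 ± 4.24 CPM to 178 ± 25.6 (SD, n = 3), the co-receptor gene Ly96 rose by 1.47 and the adaptor gene Ticam1 by 1.57. The chemokine receptor gene Cxcr4 fell by 1.98 and the kinase gene Irak1 fell by 0.48. Ager, the gene of the HMGB1 receptor RAGE, rose by 2.20 ± 0.71 with an adjusted p of 0.0198, from counts of 3, 8 and 1 to 22, 22 and 14, and by 3.17 without control replicate 2. It did not pass without control replicate 1 (0.0742), control replicate 3 (0.112), repletion replicate 1 (0.0572) or repletion replicate 2 (0.0639), with a range of 0.0160 to 0.112 over its alternatives. Hmgb1 overlaps other genes and shares sequence with Gm21596, so its value is uncertain.

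Endocytosis genes also moved both ways. Of 47 of them, 11 rose and 9 fell (11 and 9 adjusted over the list alone), with a camera adjusted p of 0.603, a median of -0.01 and a mean of 0.10. Cav1 (chromosome 6, 17306335 to 17341452), the main structural gene of caveolae, went from 438 ± 22.9 CPM to 688 ± 63.7 (SD, n = 3), Cav2 and Cavin2 rose by 0.74 and 0.68, and Ehd2 and Ehd4 rose by 1.15 and 0.70. Of the other tested cavin genes of the list, Cavin1 had a log2 fold change of 0.20 with an adjusted p of 0.118, and passed with library size only (0.0409) and after removal of the length and GC trend (0.0165), with a range of 0.0165 to 0.358 over its alternatives. Cavin3, which overlaps Gm45667, rose by 0.36, or 0.57 after removal of that trend. It did not pass without any 1 of the 3 control replicates or without repletion replicate 2 or 3 (0.0902 to 0.225), with limma-voom (0.0501), with no filter (0.0501) or with a replicate block (0.0572), with a range of 0.00171 to 0.225 over its alternatives. The clathrin heavy chain gene Cltc rose by 0.34 ± 0.10, or 0.22 after removal of the length and GC trend. The flotillin gene Flot1 fell by 0.68. The early endosome gene Rab5c fell by 0.47, and did not pass after removal of that trend (log2 fold change of -0.28, adjusted p of 0.0547, with a range of 5.2e-04 to 0.0547 over its alternatives).

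**Figure D3:**
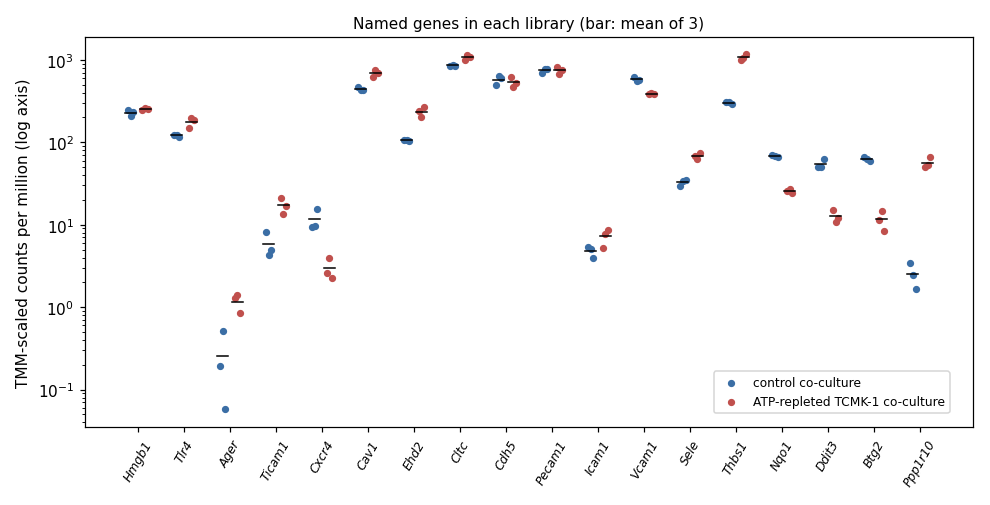
TMM-scaled CPM on a log axis for named genes, with 1 point per library of the control (blue) or repletion group (red) and black bars for the means of 3 libraries. Cav1 had means of 438 in control and 688 in the repletion group, and Hmgb1 of 229 and 255.

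Endothelial activation genes moved in both directions. Of 28 NF-kB and activation genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone), with a camera adjusted p of 0.692. The list had a median of -0.17, or -0.03 after removal of the length and GC trend, and a mean of 0.00. The leukocyte adhesion gene Sele went from 32.6 ± 2.51 CPM to 68.6 ± 5.10 (SD, n = 3) and the chemokine gene Ccl2 rose by 0.85, whereas the adhesion gene Vcam1 fell by 0.59. Icam1 had a log2 fold change of 0.59 ± 0.26 with an adjusted p of 0.0788, and passed without repletion replicate 1 (0.0241, with a range of 0.0241 to 0.283 over its alternatives). Of 27 endothelial identity genes, 12 rose and 5 fell (12 and 5 adjusted over the list alone), with a camera adjusted p of 0.0667. This list passed without control replicate 3 (0.0325), without repletion replicate 2 (0.0177) and with fry (0.0481), with a range of 0.0177 to 0.601 over its alternatives. The transcription factor genes Fli1, Sox18 and Erg rose by 1.53, 1.39 and 1.06, Clec14a rose by 1.95 and Angpt2 fell by 0.97. Cdh5, the endothelial cadherin gene, and Pecam1 had log2 fold changes of -0.10 and 0.00 with adjusted p of 0.517 and 0.994.

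Junction and coagulation genes did not pass as lists. Of 17 junction genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone), with a camera adjusted p of 0.692, a median of -0.01 and a mean of 0.06. The tight junction gene Tjp1 rose by 0.50 and Esam fell by 0.46. Of 16 coagulation and fibrinolysis genes, 6 rose and 5 fell (7 and 6 adjusted over the list alone), with a camera adjusted p of 0.603. The plasminogen activator gene Plau rose by 0.84. Thbd, the thrombomodulin gene, fell by 0.38, and did not pass without repletion replicate 3 (log2 fold change of -0.26, adjusted p of 0.103, with a range of 0.00101 to 0.103 over its alternatives).

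The remaining pathway lists did not pass camera. Of 12 inflammasome genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone), with an adjusted p of 0.692; Nlrp1a rose by 2.43, or 3.04 without control replicate 2, Gsdmd fell by 0.84 and Casp4 fell by 0.68. Of 34 hypoxia and glycolysis genes, 6 rose and 10 fell (7 and 11 adjusted over the list alone), with an adjusted p of 0.131, and the list passed as lower without control replicate 3 (0.0378) or repletion replicate 3 (0.0142), with a range of 0.0142 to 0.766 over its alternatives. Pdk1 rose by 1.09 and Ddit4 fell by 2.07. Of 20 ER stress genes, 2 rose and 6 fell (2 and 7 adjusted over the list alone), with an adjusted p of 0.144; Xbp1 rose by 0.54 and Hspa5 fell by 0.53. Of 15 heat shock genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone), with an adjusted p of 0.161 and 0.0411 with fry, with a range of 0.0411 to 0.601 over its alternatives. Hsph1 rose by 0.92, and Hspb1, which has near-identical copies, fell by 0.57, or by 0.36 after removal of the length and GC trend. Of 34 cell cycle genes, 12 rose and 5 fell (12 and 5 adjusted over the list alone), with an adjusted p of 0.224. The mitotic gene Plk1 rose by 1.09, Ccnb1, which has near-identical copies, rose by 0.86, and E2f1 fell by 0.63. The 12 that rose were mostly late cell cycle and mitotic genes, and the 5 that fell were E2f1 and DNA replication genes. The list pools several phases, so a test for a single direction does not measure such a split. This grouping was seen afterwards and was not tested. Of 24 sterol synthesis genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone), with an adjusted p of 0.312, a median of -0.25 and a mean of 0.01; Idi1 fell by 0.73. Of 19 immediate early genes, 4 rose and 2 fell (4 and 1 adjusted over the list alone), with an adjusted p of 0.603. Klf6 rose by 0.59. Jun fell by 0.44, or by 0.73 without repletion replicate 1, and did not pass without control replicate 1 (0.0603), control replicate 2 (0.0707), repletion replicate 2 (0.0974) or repletion replicate 3 (0.168), with library size only (0.0655) or after removal of the length and GC trend (0.0839), with a range of 1.6e-05 to 0.168 over its alternatives.

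Most markers of other cell types were low in both groups. In CPM of the unscaled library total, renal tubular and epithelial markers summed to 193 ± 34.9 CPM in control and 157 ± 22.4 in the repletion group (SD, n = 3), most of it from Lcn2, and 13 of 20 were below 1 CPM in every library. Of 8 tested members, 1 rose and 1 fell (1 and 1 adjusted over the list alone), with a camera adjusted p of 0.692: Cubn rose by 1.97 and Lcn2 fell by 0.54. Of 6 tested fibroblast and mural cell markers, 1 rose and the others did not pass (1 adjusted over the list alone), with a camera adjusted p of 0.745, and Col6a3 rose by 1.01. The leukocyte, lung epithelial and lymphatic lists had 3, 2 and 4 tested members, too few for a list test. On the same unscaled basis, their markers summed to 394 ± 20.6 CPM in control and 267 ± 44.4 in the repletion group for leukocytes, to 65.7 ± 10.3 CPM in control and 65.3 ± 6.33 for lung epithelium and to 92.8 ± 12.9 CPM in control and 129.9 ± 7.35 for lymphatic endothelium. Fibroblast and mural cell markers summed to 31.1 ± 2.46 CPM in control and 35.5 ± 5.26 in the repletion group. Of the leukocyte markers 1 fell and of the lung epithelial markers 1 rose (also 1 and 1 adjusted over the list alone). Cd68, which gave most of the leukocyte sum, fell by 0.63, and by 0.36 after removal of the length and GC trend. Of the lymphatic markers 3 rose and 1 fell (3 and 1 adjusted over the list alone); Reln rose by 2.46. Muc1, a lung epithelial marker, rose by 1.61, and Pdpn fell by 1.54. Muc1 did not pass without any 1 of the 6 replicates (0.0544 to 0.187, with a range of 0.0253 to 0.187 over its alternatives), and Pdpn not without any 1 of the 3 control replicates or without repletion replicate 1 or 2 (0.0546 to 0.163, with a range of 0.0257 to 0.163 over its alternatives). Neither passed with DESeq2 (0.0791 and 0.0544), Muc1 not with a replicate block (0.0565) or no filter (0.0848), and Pdpn not after removal of the length and GC trend (0.0623).

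Of the 113 named genes, 52 overlap another annotated feature, among them Ddit3, Sqstm1, Uvrag, Ctsb, Ctsl, Lamp1, Irf7, Ndufb8, Thbs1, Fli1, Angpt2, Cav1, Cav2, Jun, Reln, mt-Nd1, mt-Nd4 and mt-Nd6, and their values are uncertain. Those of Ndufb8, mt-Nd1 and mt-Nd4 lie on the same strand only, which a strand setting would not separate. However, mt-Nd1 (2751 to 3707) meets mt-Ti (3706 to 3774) only at an end, as mt-Nd4 (10167 to 11544) does mt-Nd4l (9877 to 10173). In unscaled CPM, mt-Ti held 0 in control and 0.191 in the repletion group, and mt-Nd4l held 0.545 and 7.79. Of the 13804 tested features, 6949 had groups that did not overlap, which chance gives for 10% of features. The authors' deposited table called 2822 features higher and 2481 lower at an adjusted p under 0.05, and 5021 features were called in the same direction in that table and here. Camera with its preset correlation called 8 lists here and between 4 and 9 lists in the other splits of the 6 samples into groups of 3. Those other splits mix control and repletion samples unequally, so part of the group difference stays in them. Their list counts are thus not a background free of that difference. For each of the 8 lists called here, the adjusted p with an estimated correlation was the highest of its alternatives.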

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

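No test in this part was chosen after the result was seen, as none was run. The library left out below was the one with the highest value. Features removed by the expression filter, which the comparisons above do not use, held more counts in the repletion group than in control. They made up 1978 ± 333 CPM of the unscaled library total there (SD, n = 3) against 1227 ± 67.9 in control, with each repletion library above each control library. Without repletion replicate 1, the highest at 2362, the ratio of the groups was 1.46 in place of 1.61. No technical or biological explanation was tested for these counts alone.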

How the results depend on the processing

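Removal of the length and GC trend, of features without an Ensembl identifier and of mitochondrial features were chosen after the data were seen. Of 113 named genes, 100 kept their direction and their side of the threshold under the alternatives run. Genes at an adjusted p under 0.05 numbered 2195 to 3214 higher and 1977 to 2886 lower; leaving out 1 replicate gave 2195 to 2765 and 1977 to 2745. At 2-fold or more, 1264 calls were shared with the authors' deposited table in place of 5021, because fewer genes pass that limit. Lists called higher numbered 2, but 1 to 3 without a single replicate, 0 with an estimated correlation, 4 with fry, 1 after removal of the length and GC trend and 1 without mitochondrial features, where the mitochondrial list is gone by construction. Lists called lower numbered 6, but 6 to 7 without a single replicate and 0 with an estimated correlation. Otherwise the cause was not tested. Of the 5484 called genes, 4540 kept their call and direction after removal of the length and GC trend, and 1 turned to the opposite call. Leaving out 1 replicate kept 4043 to 4870 of the 5484.

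Values near 0 changed sign. Pecam1 was 0.0069 with RLE factors, 0.061 with library size only, 0.011 with a minimum of 1 CPM, 0.0072 with protein-coding genes only, 0.0016 without features lacking an Ensembl identifier, and -0.082 to 0.066 without a single replicate. mt-Co1 was 0.071 after removal of the length and GC trend and -0.176 to 0.033 without a single replicate. The median of the junction list was -0.099 to 0.147 and that of the immediate early list -0.038 to 0.196 without a single replicate, and that of the fibroblast list was 0.18 after removal of the trend, with camera pointing the other way. With a replicate block, 2485 genes were higher and 2353 lower. The deviations of same-numbered samples had correlations of -0.076, -0.033 and 0.055, and not every sample correlated best with its own number. No shared effect of the number was thus visible. With 3 samples per group, this cannot show whether same-numbered samples were prepared together. Of simulated 1.5-fold changes 37.3% were recovered. The simulation gave 131 calls against 5484 in the data, which made its adjusted threshold stricter. That share can thus understate the recovery in the data. Changes of that size can still be missed here, but how often was not measured.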

Other observations

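The test on mt-Rnr1, the matching of far features on abundance, the comparison of downstream with other near features, the 5 lists of the next paragraph and the removal of the length and GC trend were chosen after the results were seen.

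Several genes of transcription termination were higher in the repletion group. Zc3h4 rose by 3.21, Armc5 by 2.55, and the Integrator subunit genes Ints3 and Ints6 by 2.20 and 1.76. Of 27 Integrator and termination genes 12 rose and 6 fell, with a median log2 fold change of 0.15 (camera adjusted p of 0.00894, adjusted p = 0.214 with an estimated correlation). The lists of this paragraph were drawn up after values of these data were seen. Their camera p-values are thus descriptive and give no independent support. Of 47 cytosolic ribosomal protein genes 41 fell and the others did not pass (camera adjusted p of 6.4e-16, adjusted p = 0.124 with an estimated correlation). The median of this list went from -0.54 to -0.36 after removal of the length and GC trend (camera adjusted p of 5.2e-09). Rps27 and Rpl37 fell by 1.04 and 0.92, but have near-identical copies. Zc3h4, Armc5 and Ints6 overlap other annotated features, so their values are uncertain too. Of 31 proteasome genes 16 fell and 1 rose (camera adjusted p of 1.4e-04, adjusted p = 0.176 with an estimated correlation). The proteasome median went from -0.29 to -0.15 after removal of the length and GC trend (camera adjusted p of 0.0197). Of 17 YAP target genes 8 rose, among them Ctgf, Tgfb2 and Cyr61, which are also in the TGF-beta list (camera adjusted p of 1.4e-04, adjusted p = 0.0662 with an estimated correlation). Of 26 splicing factor genes 11 rose, Srsf3 3.03-fold, and 4 fell (camera adjusted p of 0.0103, adjusted p = 0.285 with an estimated correlation), with an adjusted p of 0.0923 after removal of the length and GC trend. Protein-coding genes among the longest 10% had a median log2 fold change of 0.31 and those among the shortest 10% one of -0.19. Across 11682 protein-coding genes, which are not independent replicates, fold change and length had a Spearman rho of 0.245.

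The 10 splits of the 6 samples into groups of 3 are too few for a share under 0.05. Splits other than the real one mix control and repletion samples unequally. Part of the group difference thus stays between their groups, and the rest widens the spread within them. Their counts, among them 0 genes, do not measure chance, and no conclusion is drawn from them. For genes, 1 split, the real one, gave 5484 calls; the highest of the others was 0 in edgeR's quasi-likelihood test, with 67 to 459 genes at an unadjusted p under 0.05. For calls of at least 2-fold, 1 split gave 1421, and the highest of the others was 0. For gene lists, 4 splits gave at least the 8 calls of the real one, and the highest of the others was 9.

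Of 12 tested mitochondrial mRNAs 10 rose, mt-Co1 and mt-Co2 did not pass, and both mitochondrial rRNAs fell. Carry-over of DNA would add the same reads per kilobase to every mitochondrial gene, which is argued against by mt-Rnr1, with a log2 fold change of -1.83 and 809 unscaled CPM per kilobase in the repletion group, less than the 1898 that mt-Nd1 gained. Reads shared with annotated nuclear copies are argued against as the whole source. The 3 mRNAs without such a copy, mt-Nd1, mt-Nd6 and mt-Cytb, had a median log2 fold change of 2.36. Copies outside annotated transcripts were not sought, so reads shared with those are not covered. A response of the endothelial cells to the co-culture and a difference in how the kinds of mitochondrial RNA were captured were not tested, and both stay open.

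The antioxidant, integrated stress response, p53, lysosomal, interferon and nuclear respiratory chain lists were lower together. A trend with gene length and GC content is argued against as the whole cause, since 6 of the 6 lists were still called lower by camera after a correction for it. The correction took the Spearman rho with length across protein-coding genes from 0.245 to -0.0049, but the slope per SD of log2 length over tested features, non-coding ones included, from 0.0807 to -0.0649, so it did not level that slope. A trend with abundance and length is argued against too as the whole cause, since 6 of 6 medians lay below the central 95% of matched random lists. Matched lists had a median of -0.21 for the respiratory chain list, against its own -0.47, and of -0.16 to -0.10 for the others. The random lists drew genes independently, and the 6 lists were chosen as lower, so the central 95% can be too narrow. A biological difference between the groups stays open and was not tested; the list calls were lost with an estimated correlation, and the ER stress and heat shock lists did not pass camera (adjusted p of 0.144 and 0.161).

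Non-coding features were higher in the repletion group: of 1253 tested, 287 rose and 98 fell, with a median log2 fold change of 0.39 against 0.27 for protein-coding genes matched on abundance. Carry-over of genomic DNA is argued against, since the excess over silent receptor genes would give a median of 0.110% of the excess reads of the 287 features. Unspliced RNA of host genes stays open. The 351 features over 10 kb from tested protein-coding genes, the far features, had a median of 0.23. Its bootstrap interval began at 0.15, which passes the bound set in advance against this explanation. But protein-coding genes matched to the far features on abundance had a median of 0.21 (0.11 to 0.32). The far median thus lay within the range that abundance alone gives. The 579 features inside or overlapping tested protein-coding genes had a median of 0.37. Other features within 10 kb had 0.57 and downstream ones 0.72. Read-through past gene ends stays open: 96 features downstream of genes had a median 0.49 above that of the far features (permutation p of 3.1e-04, 100000 permutations), but the 227 other features within 10 kb of genes had one 0.34 above it, and the downstream median exceeded theirs by 0.15 (permutation p of 0.469). A trend with abundance and a biological difference between the groups also stay open, for the far features.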
